A study of Mus musculus with 8 samples.

How the data were processed

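Total RNA from the tibialis anterior of male C57BL/6 mice was extracted with TRIzol and column purification with DNase treatment, amplified with an Ambion TotalPrep kit and labelled with biotin, per the labels' protocols. The 8 arrays have 1 colour and fall into a control plasmid group and a p21 plasmid group of 4 each, by the titles in the labels. The values are log2 intensities as deposited by the authors, in a table of 25697 Illumina probes. The array software, the background correction and the normalization are not given in the sources used here. The log2 scale and the normalization were therefore read from the deposited values. The sorted values of the 8 arrays differed by at most 0.00073, so the deposited table had already been quantile normalized. The lowest value was 8.13 and the median 8.39, close to that floor, which compresses changes of dim probes. Such normalization also removes any difference in the total amount of RNA between arrays. No detection calls were used, and no probe was filtered.

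Gene names came from the platform annotation of the probes. Of all probes, 23978 had 1 symbol, 0 had several and 1719 are unnamed here. The Entrez numbers of 23962 named probes matched a RefSeq gene table, and no symbol changed through that match. No coordinates are given, since the sources used here name no genome build for the probes.

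The groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, p21 minus control, two-sided, with Benjamini-Hochberg adjustment over all probes and a threshold of adjusted p 0.05. Single probes of the named genes and the list means were also tested with an exact two-sided permutation test over all 70 regroupings. That test takes the arrays as unpaired, and its p-values were not adjusted. Each gene was represented by its probe with the highest mean over the 8 arrays, and the text says how many of its probes passed where they disagree for the genes of largest change. Gene lists, 34 in all with 870 names, of which 752 were measured and 118 were not found under the name given, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation and fry, whose directional p tests whether a list moves one way on balance. Of the lists, 9 hold markers of other cell types in muscle. Some markers, such as Thy1, sit on 2 lists, and muscle also expresses some of them.

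The lists, the tests and the rule for naming genes were set before the data were examined. The rule names every Cdkn1a probe, Smox, and up to 12 genes per direction with the largest change among probes past the threshold whose groups do not overlap and whose higher mean is above the median of all values. For Smox a dimmer probe met the condition on overlap. Gene models without a symbol of their own are counted and not named. In each list with camera adjusted p under 0.05 or with 3 or more members past the threshold, up to 4 members with the smallest p are named. Members of small counts outside this rule are marked as picked after their values were seen.

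Both groups are numbered 1 to 4 in the labels, which do not say what a number marks. Deviations from the group means correlated across probes between arrays of the same number at 0.483, 0.264, 0.212 and 0.181. All 4 lay over the 0.1 set as the minimum for reading the numbers as pairs, so this pairing comes from the data and not from the labels. It is uncertain, since control replicate 3 correlated more with p21 replicate 4 (0.448) and control replicate 4 with p21 replicate 2 (0.297). The p21 replicates 2 and 4 likewise correlated most with control replicates 4 and 3. The fit with the replicate number as a block is given beside a result where it changes a call or moves a count by over 1.5 times.

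Alternatives were the replicate block, repeated quantile normalization, median centring, probes brighter than the median probe, eBayes without the trend or with robust estimation, array weights, an offset of 16 on the linear scale, other thresholds, the mean of a gene's probes, and leaving out each array in turn. A background-subtracted scale, the counts of each list without p21 replicate 2 as an array that stands apart, and 12 gene families were added after seeing the data. The steps were tested on simulated data with the same number of arrays and 25697 probes. Of 100 probes changed by 0.5 on the log2 scale 77% were recovered, and of 100 changed by 1 98%, with 14 false calls among 189. The changed probes and the genes of the simulated lists were drawn from probes brighter than the median probe. Recovery of dim probes was therefore not tested. Camera recovered 2 of 2 shifted lists with either correlation and made 0 false calls in a run of 34 lists. The simulated probes varied independently, while the macrophage list, for example, had an estimated correlation of 0.48 between genes. False list calls that arise from correlated genes were therefore not tested by the simulation. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.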

Results

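Gene expression was measured on Illumina bead arrays, which carry 1 or more probes for each gene they cover, in the tibialis anterior, a muscle of the lower hindlimb. The muscles came from male C57BL/6 mice aged 8 weeks and were collected 7 days after transfection with a plasmid for p21 or with a control plasmid. There were 4 arrays per group, called control replicates 1 to 4 and p21 replicates 1 to 4. p21, the product of Cdkn1a, inhibits cyclin-dependent kinases, and the comparison asks which muscle transcripts differ when it is overexpressed. Each array gave log2 intensities for 25697 probes, of which 23978 carried 1 gene symbol, for 16593 genes. Every array had a median of 8.39 and a range of 8.13 to 15.27. The labels say that muscles of both legs were taken but not which samples share a mouse, so the p-values measure the spread between these samples, which may be technical. With 4 arrays per group, the number of arrays limits the precision. Levels below are mean log2 intensities ± SD (n = 4 per group), and changes are p21 minus control on the log2 scale ± SE.

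Cdkn1a, which encodes p21, read higher in every p21 muscle than in every control muscle. A probe in the untranslated part may miss a plasmid that carries only the coding sequence. The probes may thus read the plasmid transcript, the muscle's own Cdkn1a or both, which were not told apart. The brightest of the 3 Cdkn1a probes read 10.01 ± 0.19 in controls and 11.44 ± 0.21 in p21 muscles, a change of 1.43 ± 0.12 or 2.70-fold (adjusted p = 0.00042). The other Cdkn1a probes rose by 0.99 ± 0.10 and 1.21 ± 0.11. For each of these probes the exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 unpaired arrays allow. If the replicate numbers mark pairs, the 8 splits that part all pairs are too few for an exact p under 0.05. This limit holds for every exact permutation p below.

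The largest rises included genes of immature or denervated muscle and genes that macrophages express. Myh8, the neonatal myosin heavy chain, rose from 11.76 ± 0.81 to 14.46 ± 0.56, or 6.48-fold (adjusted p = 0.0045). Sln, which encodes the calcium pump inhibitor sarcolipin, rose 6.30-fold. Chrng, the fetal subunit of the acetylcholine receptor, rose 4.49-fold, from 8.86 ± 0.23 to 11.03 ± 0.15 (adjusted p = 1.4e-05). Chrna1, another subunit of that receptor, rose 3.12-fold, and Myl4, the embryonic myosin light chain, 4.29-fold. Igf2, a growth factor, rose 3.57-fold, the tubulin gene Tubb2b 3.59-fold and C1qtnf3 3.07-fold. Among genes that macrophages express, Gpnmb rose 4.07-fold, Ms4a7 3.92-fold, Apoe 3.72-fold and Lgals3, or galectin-3, 3.07-fold. In Gpnmb 1 of 4 probes passed the threshold, in Tubb2b 4 of 6 and in Chrna1 2 of 3. All 12 genes kept adjusted p under 0.05 without p21 replicate 1, 2 or 3. Gpnmb was lost without control replicate 1, 2, 3 or 4 or p21 replicate 4, and Apoe without control replicate 1 or p21 replicate 4. Robust eBayes ended the calls of Gpnmb and Apoe, and eBayes without the trend that of Gpnmb.

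The largest falls included enzymes, ion channel subunits and a myosin light chain. Smox, which encodes spermine oxidase, fell in all 5 of its probes, and its brightest probe went from 12.86 ± 0.29 to 11.46 ± 0.85 or 2.64-fold lower (adjusted p = 0.028). In that probe the groups overlapped (exact permutation p = 0.0571), while the other Smox probes showed no overlap. Dusp26, a protein phosphatase, was 2.53-fold lower (adjusted p = 0.0496), and Myl3, the light chain of slow and ventricular myosin, 2.29-fold lower. Scn4b, a sodium channel subunit, was 2.20-fold lower, and the potassium channel genes Kcnc4 and Kcng4 were 2.05-fold and 1.94-fold lower. Rcan2, a calcineurin regulator, was 2.06-fold lower and Smtnl2 1.99-fold. Haus7, a microtubule-associated gene, the phosphatase gene Ppm1l, the tubulin gene Tuba8 and Magix were 1.92-fold, 1.91-fold, 1.91-fold and 1.89-fold lower. Of these 12 genes, 2, 1, 5 and 7 were past adjusted p 0.05 without control replicate 1, 2, 3 and 4, and 0 without p21 replicate 4, where limma called 159 probes of the table. With robust eBayes 4 passed, without the trend 5, and on the background-subtracted scale Dusp26 and Tuba8 were lost. Smox lost its call without control replicate 1, 2 or 3 or p21 replicate 4, with robust eBayes and without the trend, and its adjusted p ranged from 0.0059 to 0.11 over the 17 alternatives tried.

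**Figure D1:**
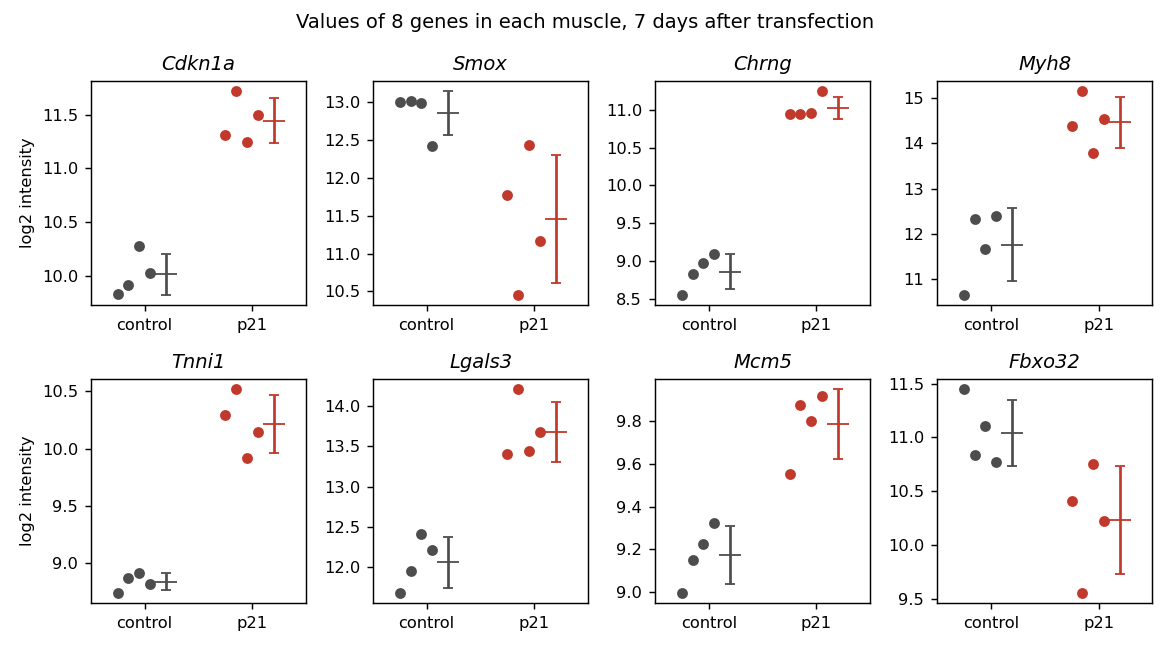
Log2 intensity of 8 genes in each control (dark points) and p21 (red points) muscle, with the mean and SD of each group (n = 4). Cdkn1a, Chrng, Myh8, Tnni1, Lgals3 and Mcm5 lie higher in all p21 muscles than in all control muscles, Fbxo32 lies lower, and the brightest Smox probe overlaps in p21 replicate 3 and control replicate 4.

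Across the array, 2064 probes passed adjusted p 0.05, with 945 higher and 1119 lower in p21 muscles. They named 750 genes that rose and 884 that fell, with no gene in both directions. Of the rises, 88 were at least 2-fold, against 11 of the falls. The groups did not overlap in 16.7% of all probes, where chance gives 2.86%. With the replicate number as a block, 3186 probes passed (1559 higher, 1627 lower), and 2034 were past in both fits. The count was 379 without control replicate 1, 391 without control replicate 2, 1032 without control replicate 3, 1291 without control replicate 4 and 159 without p21 replicate 4.

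**Figure D2:**
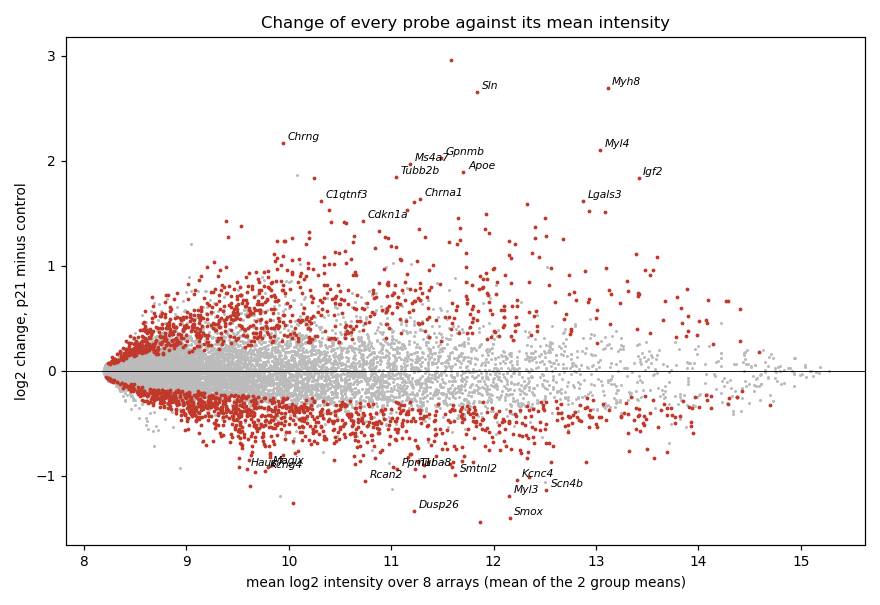
Change of every probe (p21 minus control, log2) against its mean log2 intensity over the 2 groups, with the 2064 probes past adjusted p 0.05 in red and the genes of largest change named at their brightest probe. Changes of 2-fold or more lie mostly among the rises, 88 against 11 falls.

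Of 34 gene lists fixed before the data were examined, 22 passed camera, 12 higher and 10 lower, with the preset correlation between genes. With a correlation estimated from these arrays, camera called 0 lists at adjusted p 0.05 (smallest 0.164) and 8 at unadjusted p under 0.05, and fry called 19. The calls of camera below therefore hold with the preset correlation alone. On the background-subtracted scale, added after seeing the data, the medians of 11 of the 22 lists lay over 1.5 times farther from 0, as did 7 over probes brighter than the median and 3 with array weights. None of these 3 settings turned the median of a list past camera. With an array left out, the medians of 4 of the 34 lists changed sign. The list means lay apart between the groups (exact permutation p = 0.0286) in 17 of the 22 lists and in 4 of the 12 others. These permutation p-values take the arrays as unpaired and are not adjusted over the lists. For every list below, the muscles compared are ones in which macrophage markers differed, with 15 of 22 that rose.

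Genes induced in denervated or immobilized muscle were higher in p21 muscles. Of 18 measured, 12 rose (14 adjusted over the list alone), with a median of 0.35. The size of that median depends on the scale, with 0.63 over brighter probes and 0.98 on the background-subtracted scale. Chrng, Chrna1, Myog, a myogenic transcription factor, and Ncam1, a neural adhesion molecule, rose by 2.17 ± 0.12, 1.64 ± 0.11, 1.27 ± 0.09 and 1.23 ± 0.12. The list passed camera at adjusted p = 1.5e-10, with adjusted p = 0.164 with an estimated correlation. The single member that fell was the histone deacetylase gene Hdac4 (−0.29 ± 0.06), picked after its value was seen, and that call was lost without control replicate 1, 2 or 4 or p21 replicate 4. In the same muscles the macrophage list had a median of 0.98 and the endothelial list of −0.26.

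Slow fiber genes moved both ways. Of 14 measured, 6 rose and 1 fell (6 and 1 adjusted over the list alone). The slow troponin genes Tnni1, Tnnt1 and Tnnc1 rose by 1.38 ± 0.11, 1.37 ± 0.18 and 1.46 ± 0.21, and Atp2a2, the slow-fiber calcium pump, 2.15-fold. Myl3 fell, and Myh7, the slow myosin heavy chain, had a change of −0.02 ± 0.05 (adjusted p = 0.84; Myh7 was picked after its value was seen). The list median was 0.01, from −0.008 to 0.051 with an array left out and 0.33 over brighter probes. It lay under 0 without control replicate 4 or p21 replicate 1. The slow list had camera adjusted p = 0.0126, with adjusted p = 0.164 with an estimated correlation. The fall of Myl3 was lost without control replicate 1, 2, 3 or 4 or p21 replicate 4, with robust eBayes and without the trend. In the fast fiber list 2 of 16 members fell (2 adjusted over the list alone), the calcium-binding Casq1 by −0.40 ± 0.08 and the fast myosin Myh4 by −0.44 ± 0.11. Actn3 (−0.14 ± 0.05) and Mybpc2 (−0.16 ± 0.06) missed the threshold. The fast list means lay at 14.32 to 14.45 in the 8 muscles, near the array maximum of 15.27. Whether changes of such bright probes are compressed was not tested, so small changes here need not mean stable levels. The fast list passed camera at adjusted p = 0.0473, with adjusted p = 0.267 with an estimated correlation, and missed it with the replicate block (adjusted p = 0.068). It also missed it without control replicate 1 or 4 or p21 replicate 4 (0.058, 0.081 and 0.070), with array weights (0.053), over brighter probes (0.163) and on the background-subtracted scale (0.174). Its falls numbered 1 without control replicate 1 or 3 and 0 without control replicate 2 or p21 replicate 4, and Myh4 was lost without the trend. Macrophage markers, with a median of 0.98, were higher in these muscles.

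Satellite cell and regeneration genes included 6 of 23 that rose (7 adjusted over the list alone). Besides Myog and Myh8, which the denervation list also holds, Mymk, which drives myoblast fusion, rose by 0.72 ± 0.07 and Myl4 by 2.10 ± 0.22. The list median was 0.03 and camera adjusted p = 0.0016, with adjusted p = 0.178 with an estimated correlation. Without control replicate 1 and 3 and p21 replicate 4 the median was 0.055, 0.022 and 0.060. Macrophage markers, which include no member of this list, had a median of 0.98.

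Replication and mitosis genes were higher in the muscles that received p21. Of 42 measured, 17 rose (25 adjusted over the list alone, which also called 1 fall), with a median of 0.14. The size of that median depends on the scale, with 0.26 over brighter probes and 0.60 on the background-subtracted scale. Mcm5 and Mcm6, subunits of the replicative helicase, rose by 0.61 ± 0.09 and 0.41 ± 0.07. Uhrf1, which maintains DNA methylation, and Top2a, a topoisomerase, rose by 0.45 ± 0.08 and 0.50 ± 0.10. The list passed camera at adjusted p = 4.4e-09, with adjusted p = 0.178 with an estimated correlation. The number that rose was 3, 4 and 8 without control replicate 1, 2 and 3, and 1 without p21 replicate 4. Among cyclins, their kinases, inhibitors and the RB family, with Cdkn1a left out, 6 of 19 rose and 1 fell (7 and 1 adjusted over the list alone). The kinase inhibitor gene Cdkn1c rose by 1.26 ± 0.25, the cyclin Ccnd3 by 0.58 ± 0.12, the kinase Cdk2 by 0.47 ± 0.10 and the transcription factor E2f2 by 0.41 ± 0.09. The member that fell was E2f6 (−0.61 ± 0.14), picked after its value was seen, and the rise of Cdkn1c was lost with robust eBayes. This list had a median of 0.04 and camera adjusted p = 0.0026, with adjusted p = 0.164 with an estimated correlation. Without control replicate 1 or p21 replicate 4 no member of this list was called, and without control replicate 2 and 3 the rises were 1 and 3 and E2f6 was lost. The macrophage list, with a median of 0.98, was higher in the same muscles.

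Genes of mitochondrial respiration were lower. Of 75 subunits of the respiratory complexes and ATP synthase, 16 fell and 1 rose (34 and 2 adjusted over the list alone), with a median of −0.21. Ndufb11, Ndufs7, Ndufa12 and Ndufa1, all of complex I, had changes of −0.41 ± 0.06, −0.49 ± 0.07, −0.47 ± 0.08 and −0.35 ± 0.07. Cox8a was the member that rose (0.57 ± 0.12), and it was picked after its value was seen. The list passed camera at adjusted p = 1.2e-11, with adjusted p = 0.267 with an estimated correlation. The falls numbered 3, 4, 8 and 5 without control replicate 1, 2, 3 and 4, and 2 without p21 replicate 4. No member rose without control replicate 1 or p21 replicate 4, and 2 rose without p21 replicate 1, with robust eBayes (10 falls), with the replicate block (22 falls) and over brighter probes (24 falls). In these muscles the macrophage list had a median of 0.98.

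Enzymes of the tricarboxylic acid cycle and of pyruvate dehydrogenase followed the same direction, with 9 of 21 that fell and 1 that rose (15 and 1 adjusted over the list alone). Idh3a changed by −0.71 ± 0.12, Dlat by −0.72 ± 0.13, Suclg1 by −0.42 ± 0.09 and Pdha1 by −0.42 ± 0.10, while Idh3b, picked after its value was seen, rose by 0.46 ± 0.11. The median was −0.32 and camera adjusted p = 3.0e-06, with adjusted p = 0.267 with an estimated correlation. The falls numbered 2, 2, 3 and 4 without control replicate 1, 2, 3 and 4, and 0 without p21 replicate 4, and Idh3b was lost in each of these. Of 25 genes of fatty acid uptake and oxidation, 8 fell (14 adjusted over the list alone), among them the transporter gene Slc27a1 (−0.59 ± 0.09), Decr1 (−0.49 ± 0.11), Acadvl (−0.62 ± 0.14) and Cpt2 (−0.40 ± 0.10). Their median was −0.35 and camera adjusted p = 1.2e-07, with adjusted p = 0.234 with an estimated correlation. Here 1, 1, 3 and 3 fell without control replicate 1, 2, 3 and 4, and 0 without p21 replicate 4. Beside both lists stands the rise of the macrophage list, with a median of 0.98.

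The list of mitochondrial regulators had 8 of 20 members that fell (10 adjusted over the list alone) and a median of −0.24. They included Prkaa2, a catalytic subunit of the energy-sensing kinase AMPK (−0.52 ± 0.10), and the nuclear receptor gene Esrrb (−0.48 ± 0.10). Mfn2 (−0.43 ± 0.10) and Mfn1 (−0.55 ± 0.13) act in mitochondrial fusion rather than in transcription. By camera the list had adjusted p = 0.0028, with adjusted p = 0.278 with an estimated correlation. Without control replicate 1, 2, 3 and 4 the falls were 0, 1, 4 and 4, and without p21 replicate 4 they were 0. The macrophage list median was 0.98 in the same comparison.

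Genes of glycolysis and glycogen use were lower as well, with 10 of 25 that fell (11 adjusted over the list alone, which also called 1 rise). Slc2a4, the insulin-responsive glucose transporter, changed by −0.87 ± 0.18, glycogen synthase Gys1 by −0.43 ± 0.09, glycogen phosphorylase Pygm by −0.50 ± 0.12 and its kinase subunit Phka1 by −0.55 ± 0.14. The median was −0.11 and camera adjusted p = 0.00056, with adjusted p = 0.267 with an estimated correlation. Falls numbered 0, 0, 1 and 2 without control replicate 1, 2, 3 and 4, and 0 without p21 replicate 4. With all arrays they were 2 with eBayes without the trend, where Pygm and Phka1 were lost, and 1 member rose with the replicate block. Of 16 genes of excitation-contraction coupling, 6 fell (11 adjusted over the list alone, which also called 1 rise). The chloride channel gene Clcn1 changed by −0.40 ± 0.08, the calcium channel subunit Cacnb1 by −0.37 ± 0.08, Stac3, of the triad, by −0.49 ± 0.11 and Fxyd1, a sodium pump regulator, by −0.46 ± 0.11. The median was −0.31 and camera adjusted p = 0.00078, with adjusted p = 0.267 with an estimated correlation. For this list 0, 0, 2 and 3 fell without control replicate 1, 2, 3 and 4, 0 without p21 replicate 4, and 1 rose without p21 replicate 3, with robust eBayes, with the replicate block and over brighter probes. The endothelial list, with a median of −0.26, was lower in the same muscles and the macrophage list, with 0.98, higher.

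Clock genes had 3 of 17 members that fell (3 adjusted over the list alone). These were the repressors Nr1d2 (−0.42 ± 0.09), Nr1d1 (−0.65 ± 0.17) and Cry2 (−0.18 ± 0.05), while Tef (−0.21 ± 0.09) missed the threshold. Cry2 missed it with the replicate block (adjusted p = 0.052). The median was −0.07 and camera adjusted p = 0.0183, with adjusted p = 0.164 with an estimated correlation. Without control replicate 3 or 4 the falls were 1, and without control replicate 1 or 2 or p21 replicate 4 they were 0. The median was −0.109, −0.127 and −0.115 without control replicate 3, p21 replicate 2 and p21 replicate 4, and −0.134 with array weights. Nr1d1 was lost with robust eBayes and without the trend, and Cry2 on the background-subtracted scale. Macrophage markers were higher in the same muscles, with a median of 0.98.

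Ubiquitin ligases, FoxO factors and proteasome genes of muscle atrophy showed falls in 4 of 29 members (7 adjusted over the list alone). Fbxo32, the ligase atrogin-1, changed by −0.81 ± 0.22 (adjusted p = 0.048), the conjugating enzyme Ube2b by −0.45 ± 0.11, the proteasome activator Psme4 by −0.44 ± 0.11 and the proteasome subunit Psmd11 by −0.32 ± 0.09. Trim63, the ligase MuRF1, had a change of −0.48 ± 0.14 and adjusted p = 0.061, and it was picked after its value was seen. It passed with the replicate block (adjusted p = 0.0071). The list did not pass camera (median −0.02, from −0.032 to −0.016 with an array left out, adjusted p = 0.171), although its mean was lower in all p21 muscles than in all controls (by 0.11, and 0.07 without p21 replicate 2, exact permutation p = 0.0286), and with the replicate block 8 members fell. Without p21 replicate 1 the falls were 2, and without p21 replicate 4 or any 1 of the 4 controls they were 0. Over brighter probes 7 fell. Fbxo32 lost its call with array weights, with robust eBayes, without the trend and on the background-subtracted scale, and Ube2b and Psme4 without the trend.

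Targets of p53 had 3 of 24 members that fell and none past the threshold among rises (3 and 3 adjusted over the list alone). Tigar changed by −0.29 ± 0.06, Rrm2b by −0.42 ± 0.10 and Phlda3 by −0.51 ± 0.14, while the apoptosis gene Bbc3 (0.30 ± 0.09, adjusted p = 0.066) missed the threshold. The list median was −0.00025 (−0.019 to −0.002 with an array left out) and its mean −0.017 (−0.004 without control replicate 1, −0.026 without control replicate 3 and −0.009 without p21 replicate 4), where camera pointed up at adjusted p = 0.958. In the fit with the replicate block 2 members rose, Bbc3 among them (adjusted p = 0.015), and 3 fell. Without control replicate 1 or 2 or p21 replicate 4 no member was called, and without p21 replicate 3 the counts were 2 that rose and 1 that fell. Over brighter probes 2 rose, and without the trend 1 rose and Phlda3 was lost.

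Amino acid stress genes under ATF4 had 5 of 27 members that rose and 1 that fell (5 and 2 adjusted over the list alone). The serine synthesis gene Psat1 rose by 0.63 ± 0.09, the amino acid transporter Slc7a5 by 0.64 ± 0.09, asparagine synthetase Asns by 0.43 ± 0.07 and the hormone gene Fgf21 by 0.26 ± 0.05. Atf5, picked after its value was seen, changed by −0.48 ± 0.12. The list did not pass camera (median 0.00095, from −0.008 to 0.021 with an array left out, adjusted p = 0.318), and with the replicate block 6 rose and 3 fell. The rises were 3 without control replicate 1 or 2 or p21 replicate 4, Atf5 was lost in these and without control replicate 3 or 4, and 2 fell without p21 replicate 1. Antioxidant and metallothionein genes went both ways, with 3 of 23 that rose and 2 that fell (3 and 6 adjusted over the list alone). Metallothionein Mt1 rose by 0.73 ± 0.10 and Gpx1 by 0.67 ± 0.15, while Gstm1 changed by −0.55 ± 0.11 and catalase Cat by −0.33 ± 0.08. This list did not pass camera (median −0.07, and −0.04 without control replicate 2, adjusted p = 0.171) but passed fry (0.0240), and with the replicate block 4 rose and 4 fell. Its rises were 1 and its falls 0 without control replicate 1 or 2 or p21 replicate 4, and 1 fell without control replicate 4. Over brighter probes 6 fell, and without the trend 4.

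Autophagy and lysosome genes had 4 of 26 members that rose and 1 that fell (5 and 1 adjusted over the list alone). The lysosomal proteases Ctsz and Ctsb rose by 0.82 ± 0.13 and 0.74 ± 0.15 and the lysosomal enzyme Hexa by 0.83 ± 0.20, while Ulk1, which starts autophagy, changed by −0.33 ± 0.07. The list median was −0.03 (−0.057 to −0.006 with an array left out) and its mean 0.07, where camera pointed up at adjusted p = 0.971. That mean was higher in all p21 muscles than in all controls (exact permutation p = 0.0286), but 0.03 without p21 replicate 2, and 15 of the 26 members were lower. Rises were 1 and falls 0 without control replicate 1 or 2 or p21 replicate 4, 2 rose without control replicate 3 or 4, and 2 fell without p21 replicate 1. Hexa was lost with robust eBayes and without the trend. The macrophage list, with a median of 0.98, was higher in the same muscles.

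Heat shock and unfolded protein genes had 2 of 22 members that rose (4 adjusted over the list alone), the chaperone Hsp90b1 by 0.38 ± 0.09 and the disulfide isomerase Pdia4 by 0.35 ± 0.09. Creld2 (0.23 ± 0.07) and Calr (0.30 ± 0.09) missed the threshold. The median was 0.03 and camera adjusted p = 0.0200, with adjusted p = 0.164 with an estimated correlation. The replicate block gave 5 rises, with Creld2 and Calr past (adjusted p = 0.031 and 0.020). The rises were 1 without control replicate 4 or p21 replicate 3, and 0 without control replicate 1, 2 or 3 or p21 replicate 4. They were 4 with robust eBayes and over brighter probes, and Pdia4 was lost without the trend. Camera missed the threshold without control replicate 4 or p21 replicate 3 (adjusted p = 0.057 and 0.066) and on the background-subtracted scale (0.055). The median was 0.067, 0.018 and 0.052 without control replicate 1, control replicate 3 and p21 replicate 4, and 0.194 over brighter probes. Beside this list too the macrophage median was 0.98.

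Insulin and IGF1 signaling genes did not pass camera (median −0.01, from −0.024 to −0.002 with an array left out, adjusted p = 0.958), although Igf2 and the receptor-binding adaptor Grb10 (1.12 ± 0.21) rose, 2 of 17 (2 rises and 2 falls adjusted over the list alone). The rises were 1 without control replicate 1 or p21 replicate 4, and 1 member fell without p21 replicate 2, with the replicate block or with array weights, and 2 without the trend or over brighter probes. The mean of that list was 0.16 higher (0.11 without p21 replicate 2), with all 4 p21 muscles above all controls (exact permutation p = 0.0286). However, 10 of the 17 members were lower, so the large rises of Igf2 (1.84) and Grb10 carry that mean rather than the list as a whole. Polyamine genes did not pass either (median −0.00057, from −0.016 to 0.010 with an array left out, adjusted p = 0.958). Of 11 measured, Sat1, which acetylates spermine and spermidine, rose by 0.88 ± 0.17 and Smox fell (1 and 2 adjusted over the list alone). Both calls were lost without control replicate 1 or p21 replicate 4, and that of Smox also without control replicate 2 or 3, with robust eBayes or without the trend, while 2 fell over brighter probes. Grb10 and Sat1 were picked after their values were seen. In nucleolar and RNA polymerase I genes limma called 0 of 20 (0 adjusted over the list alone), against 2 higher and 1 lower at unadjusted p under 0.05. Their median was −0.01 (−0.021 to −0.002 with an array left out) and mean 0.0090 (0.003 to 0.015 with an array left out), where camera pointed up at adjusted p = 0.799 and fry gave 0.559. A single member rose over brighter probes, where the median was 0.002, and without the trend.

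Macrophage markers formed the group with the largest median among the 34 lists, 0.98. Of 22 measured, 15 rose (20 adjusted over the list alone). Ms4a7 rose by 1.97 ± 0.23, Lgals3 by 1.62 ± 0.19, the lysosomal protease Ctss by 0.61 ± 0.08 and the complement gene C1qc by 1.49 ± 0.22. The mean of the list was 1.00 higher in p21 muscles, with all 4 above all controls (exact permutation p = 0.0286). By camera the list had adjusted p = 8.5e-12, with adjusted p = 0.178 with an estimated correlation. The rises were 9 and 8 without control replicate 1 and 2, 6 without p21 replicate 4, and, with all arrays, 8 with robust eBayes and 10 without the trend.

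Fibroblast and matrix markers had 3 of 28 members that rose (6 adjusted over the list alone), with a median of 0.37. The protease inhibitor Timp1 rose by 1.27 ± 0.22, the proteoglycan Bgn by 0.97 ± 0.19 and the collagen Col3a1 by 0.77 ± 0.17, while Mfap5 (0.74 ± 0.22) missed the threshold. The camera test gave adjusted p = 0.00030, with adjusted p = 0.506 with an estimated correlation, and fry missed the threshold (0.274). The median was 0.21 without p21 replicate 2, and the mean of the list did not separate the groups (exact permutation p = 0.171). The replicate block gave 14 rises, Mfap5 among them (adjusted p = 0.013), and without p21 replicate 4 the number was 0. Secreted factors of senescent cells had 3 of 24 that rose (4 adjusted over the list alone, which also called 1 fall), Timp1, the growth factor Tgfb1 (0.59 ± 0.11) and the cytokine Il1b (0.65 ± 0.13). Vegfa had a change of −0.68 ± 0.20 (adjusted p = 0.058, and 0.013 with the replicate block). The median was 0.17, and 0.05 without p21 replicate 2. For this list camera gave adjusted p = 0.00099, with adjusted p = 0.267 with an estimated correlation, and fry missed the threshold (0.0744), as did the list mean (exact permutation p = 0.0571). For this list 7 rose and 1 fell with the replicate block, 6 rose without p21 replicate 2, 0 without p21 replicate 4, and 1 fell without p21 replicate 1 or 3 or over brighter probes. Alongside the fibroblast and senescence lists, 15 of 22 macrophage markers rose, with a median of 0.98.

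MHC genes had 4 of 19 members that rose (7 adjusted over the list alone), with a median of 0.27. That median was 0.46 without control replicate 3, 0.60 without p21 replicate 2, 0.12 without p21 replicate 3, 0.15 without p21 replicate 4 and 0.49 with array weights. The members that rose were of antigen presentation by class II: H2-Aa by 1.05 ± 0.22, H2-Eb1 by 0.95 ± 0.25, H2-Ab1 by 0.96 ± 0.26 and the invariant chain Cd74 by 0.68 ± 0.18. Camera gave adjusted p = 0.0028, with adjusted p = 0.506 with an estimated correlation, and fry (0.268) and the list mean (exact permutation p = 0.2) missed the threshold. In the fit with the replicate block 8 rose. The number was 7 without p21 replicate 2, 1 without p21 replicate 3 and 0 without control replicate 1 or 2 or p21 replicate 4. With all arrays it was 0 with robust eBayes and 1 without the trend. The macrophage list, with a median of 0.98, was higher in the same muscles.

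Interferon-stimulated genes had 3 of 35 members that rose (5 adjusted over the list alone), the antiviral genes Xaf1 by 0.45 ± 0.09, Oas1g by 0.93 ± 0.20 and Ddx58 by 0.18 ± 0.05, while Oas3 (0.19 ± 0.05) missed the threshold. The median was 0.19 and camera adjusted p = 0.00035, with adjusted p = 0.512 with an estimated correlation, and fry missed the threshold (0.304). Without control replicate 1 and 3 and p21 replicate 2 and 3 the median was 0.12, 0.28, 0.48 and 0.11, and with array weights 0.29. The list mean did not separate the groups (exact permutation p = 0.429). The mean of the list lay at 9.91 in p21 replicate 2, under all controls, which ranged from 10.08 to 10.76, and at 10.69 to 11.01 in the other p21 muscles. Without p21 replicate 2, 16 members rose, a count added after seeing the data, and 8 rose with array weights and 5 over brighter probes. Robust eBayes ended the call of Oas1g. Oas3 passed with the replicate block (adjusted p = 0.011), where 9 rose, and without control replicate 1 or 2 or p21 replicate 4 the number was 0. T, NK and B cell markers had 2 of 21 that rose (2 adjusted over the list alone), Cd28 by 0.18 ± 0.05 and Klrd1 by 0.56 ± 0.15, while Prf1 (0.21 ± 0.07) and Cd3g (0.38 ± 0.13) missed the threshold. Their median was 0.16, and 0.09 without p21 replicate 4, and camera gave adjusted p = 0.00035, with adjusted p = 0.284 with an estimated correlation, while fry (0.0795) and the list mean (exact permutation p = 0.114) missed the threshold. For these markers 10 rose with the replicate block, with Prf1 and Cd3g past (adjusted p = 0.047 and 0.0062), 5 without p21 replicate 2, 1 without p21 replicate 1 and 0 without p21 replicate 3 or 4 or any 1 of the 4 controls. With array weights 4 rose, and with robust eBayes or without the trend 1, where Klrd1 was lost. In the same muscles 15 of 22 macrophage markers rose, with a median of 0.98.

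Endothelial markers were lower, with 6 of 18 that fell (12 adjusted over the list alone) and a median of −0.26. Egfl7 changed by −0.37 ± 0.09, Robo4 by −0.46 ± 0.11, the von Willebrand factor gene Vwf by −0.34 ± 0.09 and the vascular phosphatase Ptprb by −0.38 ± 0.10. Camera gave adjusted p = 1.4e-06, with adjusted p = 0.164 with an estimated correlation. The replicate block gave 10 falls, as did the brighter probes, Ptprb was lost without the trend, without p21 replicate 1 the number was 2, and without control replicate 1, 2 or 4 or p21 replicate 4 it was 0. Smooth muscle and pericyte markers had 3 of 13 that fell and 1 that rose (3 and 1 adjusted over the list alone). The pericyte genes Kcnj8 and Rgs5 changed by −0.42 ± 0.06 and −0.43 ± 0.08 and the smooth muscle myosin Myh11 by −0.38 ± 0.08, while Acta2, smooth muscle actin, rose by 0.78 ± 0.14. The median was −0.09 and camera adjusted p = 0.0173, with adjusted p = 0.164 with an estimated correlation. Without p21 replicate 4, 1 of these fell and 0 rose. The median was −0.14 without control replicate 3 and −0.05 without p21 replicate 1, and camera missed the threshold over brighter probes (adjusted p = 0.102). While these vascular markers were lower, the macrophage list was higher, with a median of 0.98.

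The remaining cell markers did not pass camera with all arrays at the main settings. Red blood cell markers had 2 of 6 that fell (2 adjusted over the list alone), with a median of −0.13 (−0.05 without control replicate 2) and adjusted p = 0.062. Adipocyte markers had 2 of 12 that fell (2 adjusted over the list alone), with a median of −0.08 (−0.05 without control replicate 2), adjusted p = 0.134 and list means lower in all p21 muscles (exact permutation p = 0.0286). In neutrophil markers limma called 0 of 13 (0 adjusted over the list alone), against 1 higher and 3 lower at unadjusted p under 0.05, with a median of −0.11 (−0.19 to −0.03 with an array left out), adjusted p = 0.171 from camera and 0.455 from fry. In Schwann cell markers it called 0 of 11 (1 fall adjusted over the list alone), against 1 higher and 4 lower at unadjusted p under 0.05, with a median of −0.02 (−0.07 to 0.03 with an array left out, and above 0 without p21 replicate 2 and with array weights), adjusted p = 0.359 from camera and 0.455 from fry. In the fit with the replicate block 1 neutrophil marker rose and 1 fell, and 2 Schwann cell markers fell. Red blood cell and adipocyte falls both numbered 0 without control replicate 1 or 2 or p21 replicate 4 and 1 without control replicate 3, and adipocyte falls 1 without control replicate 4 or p21 replicate 2. A neutrophil marker rose without control replicate 3 or p21 replicate 2, and a Schwann cell marker fell without p21 replicate 3. Over brighter probes 1 neutrophil marker rose and 1 Schwann cell marker fell, and with array weights 1 neutrophil marker rose. Red blood cell falls were 1 with robust eBayes or without the trend, and adipocyte falls 0 without the trend. Red blood cell markers passed camera without control replicate 4, p21 replicate 3 or p21 replicate 4 (adjusted p = 0.030, 0.046 and 0.043) and on the background-subtracted scale (0.038), neutrophil markers without control replicate 1 (0.0050), and adipocyte markers passed fry (0.0403).

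**Figure D3:**
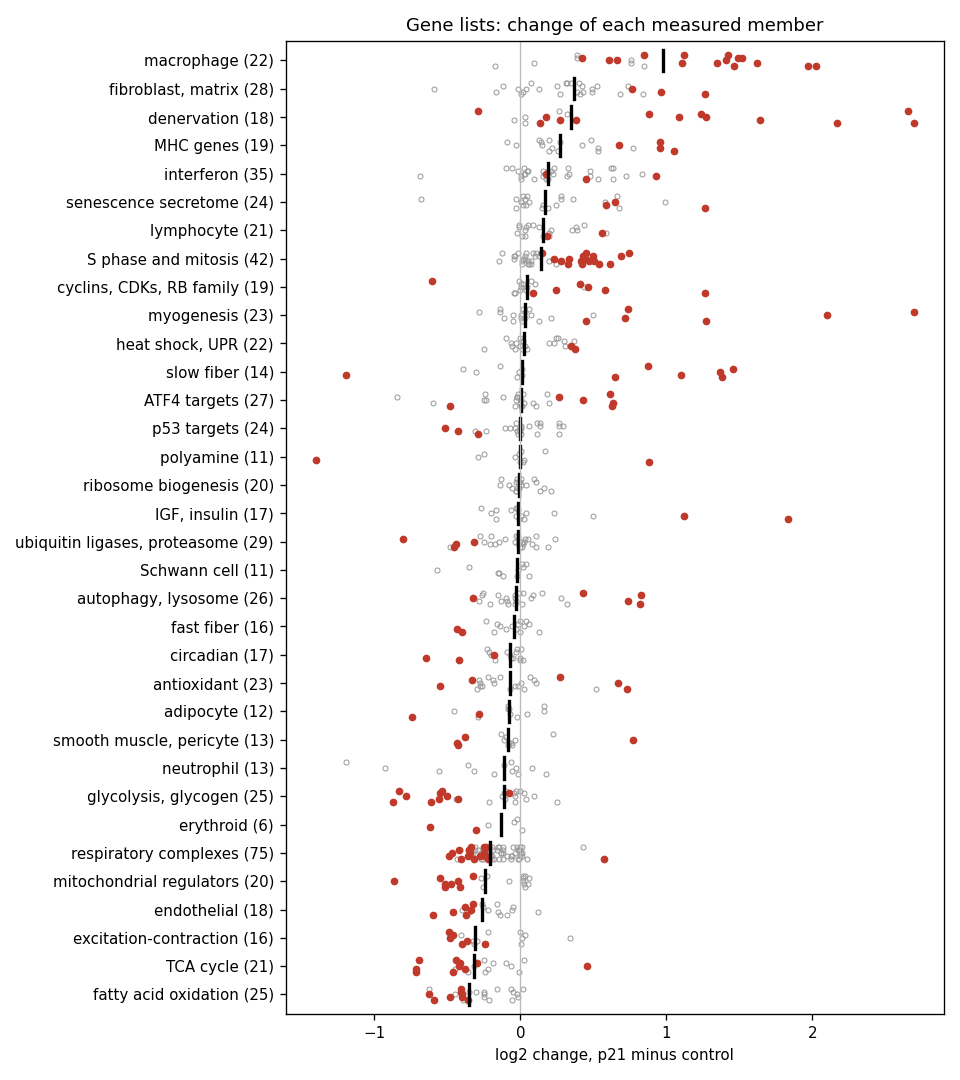
Change (p21 minus control, log2) of each measured member of the 34 gene lists, with members past adjusted p 0.05 in red, others open, and a bar at each list's median, the number measured in brackets. Macrophage markers have the highest median, 0.98, and fatty acid oxidation genes the lowest, −0.35.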

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

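The tests on p21 replicate 2, on the macrophage and endothelial markers and on the denervation genes were chosen only after the results were seen, and the splits of the arrays were set before. Of 330 sets of 4 values for the named genes and the list means, 20 held an array far from the other 3, where chance gives 16.5, about 1 in 20. Control replicate 1 was the distant array in 6 of them and p21 replicate 2 in 6.

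In control replicate 1, Tubb2b lay at 9.75 against 10.22 to 10.27 in the other controls, Tigar at 8.87, Uhrf1 at 8.63, Ncam1 at 9.02, Ndufs7 at 14.27 and Ndufa12 at 13.73. In control replicate 3, Suclg1 lay at 13.57, Actn3 at 15.07 and Fgf21 at 8.37. In control replicate 4, Smox lay at 12.43 against 12.99 to 13.02 in the other controls, Cdk2 at 9.67 and Cd28 at 8.50. In p21 replicate 4, Chrng lay at 11.25 against 10.94 to 10.96 in the other p21 muscles, and Xaf1 at 9.23. In p21 replicate 2, Col3a1 lay at 11.18 against 10.33 to 10.45, Mfap5 at 11.96, Acta2 at 13.94 and Il1b at 9.60. The mean of the insulin and IGF1 list lay at 10.10 there and that of the autophagy and lysosome list at 10.41.

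The array of p21 replicate 2 stood apart from the other p21 arrays, with a mean correlation of 0.980 with its group against 0.989 to 0.990 for the others, the highest Cdkn1a of the 8 arrays (11.72) and the lowest brightest-probe Smox (10.45). Poor quality of this array would leave its deviation unrelated to the p21 effect, and a larger response, as a hypothesis, would align it with that effect. Its deviation from 2 other p21 arrays was correlated across probes, which are not independent replicates, with the effect estimated from the remaining p21 array. The 3 such correlations ran from 0.185 to 0.401 with a mean of 0.301, where a larger response needed all 3 over 0.3 and poor quality at least 1 of 0.1 or less, and an earlier form of this test that shared arrays gave 0.281 and decided nothing either. The 2 readings cannot be told apart here, since the lowest correlation lies between those bounds and the others do not settle it. The same measure averaged 0.316 for p21 replicate 4 and 0.495 for control replicate 1, so it was not particular to p21 replicate 2. Its mean was negative for each of the remaining arrays.

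In the p21 muscles 15 of 22 macrophage markers rose, while 6 of 18 endothelial markers fell. Neither list passed camera with an estimated correlation (adjusted p = 0.178 and 0.164). A lower share of muscle fiber RNA would by itself raise the markers of every other cell type alike. The mean of the endothelial list instead changed by −0.250, with all 4 p21 values under all control values. That fall is part of the pattern to be explained, so it cannot decide on this cause. In 95.5% of the macrophage list the mean was higher in the p21 muscles, which restates the rise and decides nothing about its source. More macrophages and higher expression within the cells already present cannot be told apart, since RNA of the whole muscle holds no count of cells, and both stay open as hypotheses, as does any effect of the transfection itself that differs between the plasmids.

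Of 18 genes induced in denervated or immobilized muscle, 12 rose in the p21 muscles, the neonatal myosin Myh8 among them, and 1 fell. With an estimated correlation the list missed camera (adjusted p = 0.164). Denervation with its usual induction of ubiquitin ligases would raise Fbxo32 and Trim63. Their mean change was −0.645, with all p21 values under all control values. The margin was slim, with the highest p21 value at 10.52 (replicate 3) and the lowest control value at 10.57 (replicate 4). Trim63 alone missed the threshold, and Fbxo32 lost its call in several alternatives. The test was chosen after these falls were seen. The muscles were also collected at a single time, so an earlier rise would be missed. The test therefore cannot decide on denervation, which stays open as a hypothesis. Regeneration from satellite cells may also contribute, as a hypothesis. The median change of Pax7, Myf5 and Myod1 was 0.0706, but their control means of 8.24, 8.21 and 8.79 lay under the upper quartile of all values, 9.10, too near the floor to decide. An effect of p21 on the fibers themselves, which the design names, was not separated from these.

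The count of 2064 probes past the threshold was reached in 1 of the 35 splits of the 8 arrays, the real one. The highest of the others was 1 probe, so chance is unlikely to give that count if the arrays are unpaired. The 22 gene lists were also reached in 1 of 35 splits, but every other split called lists too, from 2 to 20. With so small a margin, the list count says little about chance. Read as pairs, the real grouping is 1 of the 8 splits that part all 4 pairs, which are too few for a share under 0.05. Among those 8 it gave 2064 probes, 22 lists and, with the replicate block, 3186 probes, and the highest of the others gave 0, 20 and 0.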

How the results depend on the processing

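The 2064 probe calls kept their sign in every alternative that tested them, which says little about stability. In 1995 of them the groups did not overlap, so leaving out an array could not turn the sign. The replicate block and the variance models of eBayes leave the change itself as it was. The replicate block gave 3186 probes (1559 higher, 1627 lower), a limit of adjusted p 0.10 gave 3490 and a minimum of 1.5-fold 526, the last 2 by construction. With an array left out, the count ranged from 159 to 2162, with 130 to 1032 higher and 29 to 1172 lower. It was 379, 391, 1032 and 1291 without control replicate 1, 2, 3 and 4 and 159 without p21 replicate 4, which left 29 of 114 named calls. The cause was not tested. The other probe alternatives, including the background-subtracted scale added after seeing the data (2121), gave 2000 to 2945 probes. Of the 114 named calls, 94 were kept with robust eBayes and 91 without the trend. Gene lists numbered 22, and 0 with an estimated correlation in camera (8 at unadjusted p under 0.05, 19 by fry), 20 to 22 in the other alternatives and 21 to 22 with an array left out. Cdkn1a rose by 1.34 to 1.52 with an array left out and passed in all 17 alternatives. Repeated quantile normalization and median centring moved nothing, since the arrays already share a distribution, and say nothing about stability. The variance models of eBayes do not enter camera. Besides the calls named in the report, the replicate block changed no list call, and of the 125 named genes it lost 1 call and added 8. Most values lie near the floor of 8.13 (median 8.39), so changes of dim probes are compressed.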

Other observations

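The gene families in this part, taken by symbol prefix, and the muscle-by-muscle values were chosen only after the results were seen. Mitochondrial ribosomal proteins were lower, with 9 of 76 that fell and a median of −0.17. Mrps21 changed by −0.47 ± 0.11 (SE) and Mrpl42 by −0.41 ± 0.10. Camera gave adjusted p = 1.1e-10, with adjusted p = 0.194 with an estimated correlation. Cytosolic ribosomal proteins went the other way, with 11 of 59 that rose and a median of 0.11, Rpl3 by 0.76 ± 0.13 and Rpl13a by 0.51 ± 0.10. For these camera gave adjusted p = 5.8e-07, with adjusted p = 0.194 with an estimated correlation. The mitochondrial falls were 0 without control replicate 1 or 2 or p21 replicate 4, 1 without control replicate 3 and 2 without control replicate 4, and 16 with the replicate block or without the trend. The cytosolic rises were 2, 1, 3 and 6 without control replicate 1, 2, 3 and 4 and 0 without p21 replicate 4. The macrophage list, with a median of 0.98, was higher in the same muscles.

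Tubulins changed in both directions, with 5 of 16 that rose and 2 that fell. Tubb6 rose by 1.54 ± 0.12, Tubb2b by 1.84 ± 0.16, Tuba1b by 0.91 ± 0.14, Tuba1a by 0.82 ± 0.13 and Tubb5 by 0.92 ± 0.17, while Tuba4a changed by −0.72 ± 0.16 and Tuba8 by −0.93 ± 0.26. Camera missed the threshold for this family (adjusted p = 0.126). Both falls were lost without control replicate 1, 2 or 3 or p21 replicate 4, and 1 was lost without control replicate 4, without the trend and with robust eBayes. Cathepsins, the lysosomal proteases, had 5 of 18 that rose, among them Ctsh by 1.21 ± 0.18 and Ctsc by 0.85 ± 0.13. Camera gave adjusted p = 0.0387, with adjusted p = 0.194 with an estimated correlation, and Ctss is also on the macrophage list, whose median was 0.98. In the 8 other families, the collagens, mitochondrial carriers, potassium channels with their regulators, actin-binding proteins, myosins, Rab GTPases with Rab-interacting proteins of the same prefix, phosphatase subunits and transporters of the glucose and monocarboxylate families, 27 of 340 members rose and 27 fell. Of these families mitochondrial carriers passed camera (adjusted p = 0.0163, and adjusted p = 0.194 with an estimated correlation), with 5 of 39 that fell and 2 that rose. The even total sums unlike families. Of 26 actin-binding proteins 6 rose and 0 fell, and of 80 potassium channel genes 3 rose and 8 fell. Both families missed camera (adjusted p = 0.0616 and 0.123). Without p21 replicate 4, no actin-binding call and 1 potassium channel fall remained. Over the 8 families the rises and falls were 8 and 5 without control replicate 1, 6 and 3 without control replicate 2, 15 and 14 without control replicate 3, 4 and 3 without p21 replicate 4, and 41 and 41 with the replicate block. For the mitochondrial carriers they were 1 and 2 without control replicate 1 or 2 or p21 replicate 4, 2 and 3 without control replicate 4, 2 and 8 without p21 replicate 1, and 3 and 9 with the replicate block.

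In p21 replicate 2 several genes of the interferon response lay far below every other muscle. Igtp, an immunity-related GTPase, read 10.55 there against 13.63 to 14.65 in the other 7 muscles. Cxcl9, a chemokine, read 11.21 against at least 12.35, and the guanylate-binding protein gene Gbp2 11.38 against at least 12.83. The same muscle had the highest macrophage list mean, 11.49 against 10.88 to 11.22 in the other p21 muscles.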
